A study of Drosophila melanogaster with 4 samples.

How the data were processed

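RNA of whole Drosophila melanogaster embryos was measured on 4 Agilent arrays of 2 colours. Per the labels, eggs were laid for 4 h, embryos were kept for 16 h at 25 °C, and total RNA was extracted with TriPure, treated with DNase, amplified from an oligo dT primer and labelled with Cy3 or Cy5 together with spike-in RNAs. Per the labels, w1118 RNA was labelled with Cy3 and DHR3 mutant RNA with Cy5 on every array, and the replicates are biological. The scans were processed with Agilent Feature Extraction 9.5.1.1, per the file headers and the submitters' processing notes. The probe design was placed on genome build dm3, per the file headers. The mean spot signal and the median local background were deposited as intensity values that had not been background-subtracted or normalized, per the file headers. The deposited processed intensity was background-subtracted, detrended and dye-normalized by Feature Extraction, and the deposited log10 ratio is that of red over green processed signal, per the file headers. The authors' series table holds log2 values; its scale and direction were found by setting it against the log10 ratios, with a slope and Pearson's r of 1.00 over 13675 bright probes on each array, so it holds log2 of Cy5 over Cy3. Its column medians were -0.090, -0.078, -0.14 and -0.089, and any further centring is not given in the sources used here. Columns of per-sample values not used numbered 0.

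Each array had 45020 spots, of which 43603 were not controls. The median control signal (Cy3) was 558, 545, 525 and 586 on replicates 1 to 4, and the median mutant signal (Cy5) was 1045, 1042, 981 and 770. Saturated spots numbered 0 in Cy3 and at most 8 in Cy5. The spread of 4 arrays sets the precision. All arrays were on 1 slide, so no slide effect could be fitted. The slope of observed on expected spike-in log ratios that Feature Extraction wrote in the file headers was 0.705 to 0.742 (r 0.981 to 0.987).

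Signals were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 (R 4.3.3, data.table version 1.17.8), with control spots at weight 0 and then left out, and outlier spots left out. Spots of a probe were averaged, a probe was kept where it was well above background on at least 3 of 4 arrays in Cy5 or on at least 3 of 4 in Cy3, and the probes of a gene name were averaged. Of 32162 probes 24165 were kept. The arrays name 24318 genes, of which 13498 were matched to the gene table of Release 6 plus ISO1 MT by locus tag, transcript name, synonym, accession or symbol, and 10820 were not. Names are those of the array files, with current names beside them. That table was used only for names and for the order of neighbouring genes, and coordinates are those of dm3 in the files. No dm3 gene models were used, so exon and UTR positions were not analysed here. Under 69 gene names, probes lay on more than 1 chromosome.

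Log2 ratios of mutant over control were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, so the array pairs the mutant and control RNA. Each value in the text is a log2 ratio unless stated, with the SD over 4 arrays. The exact sign-flip test cannot give a p under 0.125 with 4 arrays. On data simulated for this comparison with 17887 genes, 71% of genes changed by 0.5 on the log2 scale and 92% of those changed by 1 were recovered, 5.23% of calls were false, and 0 genes were called where no gene was changed. In the simulation only 100 genes were changed by each size, noise was independent between genes, and no gene had a dye bias of its own. These rates need not hold for the measured arrays, where 54.6% of genes passed. Where a fold is given for a gene with no control signal well above background, it compares the mutant mean with a control level. That level is the higher of the dim probe's own control signal and the lowest control signal among probes well above background. Such a fold is not a strict lower limit.

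The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The 28 gene lists cover ecdysone-response transcription factors, ecdysteroid synthesis and turnover, RR-type cuticle proteins, Tweedle proteins, the Osiris family, peritrophin-like proteins, chitin synthesis and modification, catecholamine, melanin and sclerotization genes, tracheal development, pickpocket channels, septate junctions, muscle, neurons, glia, neuropeptides, midgut enzymes, fat body, hemocytes, salivary gland, germ cells and yolk, glycolysis, cytoplasmic ribosomal proteins, heat shock proteins, replication and cell cycle, cell death, antimicrobial and peptidoglycan-recognition proteins, cytochrome P450 genes and glutathione S-transferases; the genes next to DHR3, 15 on each side, made a further list. Lists were tested with camera (preset correlation 0.01, and an estimated correlation as an alternative) and adjusted over 29 lists, and fry p-values were not adjusted over lists. The text names DHR3 and ftz-f1, the 10 largest increases and the 10 largest decreases with adjusted p under 0.05 and 1 sign on all arrays, list members with the smallest p-values or past the threshold, and neighbours of DHR3 that passed; features with only a transcript or probe identifier were counted and not named.

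The alternatives were no background correction, a normexp offset of 10, Agilent's log ratios, the authors' series table, median centring without loess, scale normalization between arrays, no filter, a filter on both channels on all arrays, the brightest probe of each gene, an intensity trend with robust variance, array weights, a fit without the replicate block (channels as separate samples), leaving out each replicate, an adjusted p under 0.01, a change of at least 1.5-fold, and 5 or 30 genes on each side of DHR3. The left and right neighbours alone, and the genes up to 53 places to the right, were added after seeing the data.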

Results

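Gene expression was measured in whole embryos of Drosophila melanogaster that were 16 to 20 h old, in mutants of the nuclear receptor gene DHR3 and in the control strain w1118. DHR3, named Hr46 in the array files and Hr3 in current annotation, encodes an orphan nuclear receptor that is induced by the steroid hormone ecdysone and activates ftz-f1 at the onset of metamorphosis. By the series title, the mutants carried a mutant DHR3 allele over a deficiency, a chromosome 2 lacking a segment of its right arm. Each of 4 arrays held cRNA from mutant embryos labelled with Cy5 and cRNA from control embryos labelled with Cy3, and dyes were swapped on 0 arrays. The labels call the arrays 4 biological replicates, so p-values measured the spread between these replicates, and the number of arrays limits the precision. The share of spots well above background was 69.5% to 76.3% in the control channel and 71.9% to 80.1% in the mutant channel, and was lowest in both on replicate 3. After the filter on dim probes, 17887 gene names were tested, of which 11780 matched a gene of the current annotation.

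The probes of DHR3 moved in different directions, with 1 lower and 1 higher in mutants past the threshold, and the transcript of ftz-f1, the textbook target of DHR3, fell by 0.80 on the log2 scale (SD 0.23, SE 0.091, n = 4 arrays), and was 1.75-fold lower in mutants. The mean over the DHR3 probes was -0.046 on the log2 scale (SD 0.059, n = 4; -0.054, 0.038, -0.10 and -0.065 on replicates 1 to 4), with an adjusted p of 0.458 (limma, Benjamini-Hochberg). This mean averages probes that went both ways, and with the brightest probe alone DHR3 was at -0.61 (limma adjusted p = 0.000257). On chromosome 2R of dm3, the probe at 6093570 to 6093629 was at -0.61 and the probe at 6094941 to 6095000 at 0.35, with limma adjusted p over probes of 0.000262 and 0.00228. The probe at 6094532 to 6094591 (-0.058) and the probe at 6095591 to 6095712 (0.14) did not pass, and the probe at 6120823 to 6120882 was not well above background in either channel. The position of the lesion in DHR3 and the ends of the deficiency are not given in the labels, so these probes do not check the genotype. The ftz-f1 probe, at 18745763 to 18745822 on chromosome 3L, was lower in mutants on 4 of 4 arrays (-1.13, -0.76, -0.72 and -0.60), with an adjusted p of 0.000542 in limma. The exact sign-flip test of ftz-f1, two-sided, gave p = 0.125, the smallest that 4 arrays can give.

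Among the ecdysone-response transcription factors, which include early genes of the hormone cascade, Eip74EF (-1.03, SD 0.36), Eip75B (-0.78, SD 0.18), Eip78C (-0.72, SD 0.15) and the hormone receptor gene EcR (-0.44, SD 0.035) fell, as did ftz-f1. As many members rose: Eip93F (0.74, SD 0.062), the early gene br (0.37, SD 0.33), crol (0.29, SD 0.064), Blimp-1 (0.28, SD 0.12) and Hr38 (0.27, SD 0.041). The call of br was lost without replicate 2 (0.36) or 3 (0.44), with a normexp offset of 10 (0.40), with Agilent's log ratios or the deposited table (0.42 in both), with no filter on dim probes (0.32) and with no replicate block (0.37). That of Hr38 was lost with its brightest probe and with the filter on both channels (0.14 in both), and Eip93F stood at 1.73 with Agilent's log ratios and with the deposited table. Of 16 measured, 5 were higher, 5 lower and 6 not past the threshold, and the counts were 5 higher and 5 lower adjusted over the list alone. The list did not pass in limma's camera test, with the preset correlation or with an estimated correlation (adjusted p = 0.947 with the latter). Of 9 genes of ecdysteroid synthesis and turnover, 4 were higher and 1 lower, with 4 and 1 adjusted over the list alone. The lower gene was shd, which encodes the enzyme that converts ecdysone to the active 20-hydroxyecdysone (-0.71, SD 0.35), and CG40050, now named nvd, a gene of cholesterol conversion, was higher (0.36).

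**Figure D1:**
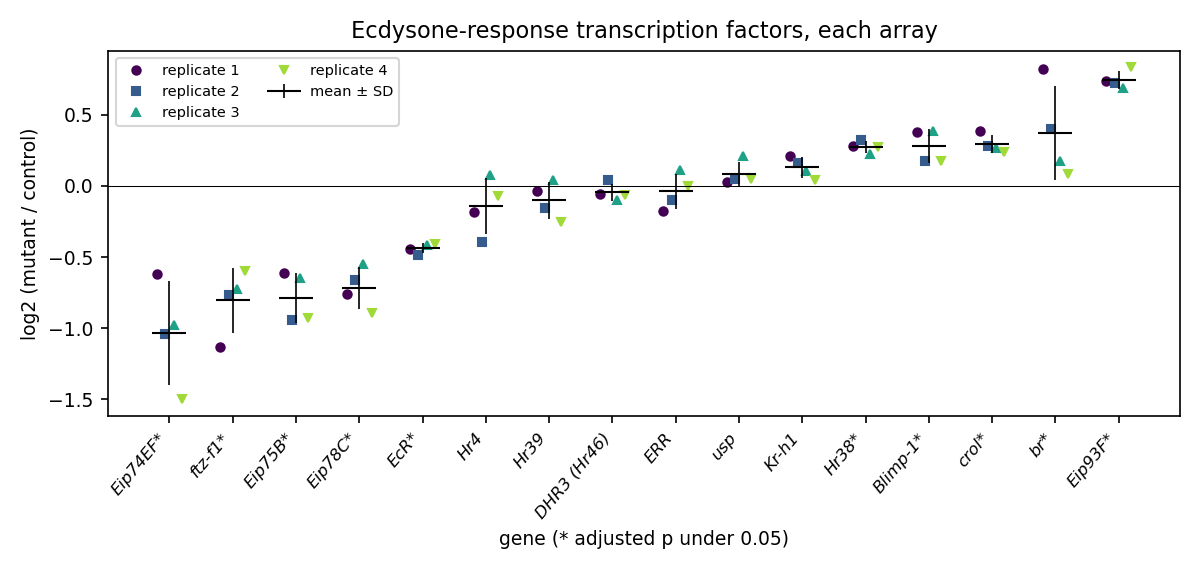
The log2 ratio of mutant over control (vertical axis) of each measured ecdysone-response transcription factor on the 4 arrays (points, 1 marker shape per replicate), with the mean and SD in black. Eip74EF lies at a mean of -1.03 and ftz-f1 at -0.80, below 0 on every array, and DHR3 lies at -0.046.

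Differences between mutants and controls extended over much of the transcriptome. Of 17887 genes, 9773 (54.6%) passed an adjusted p of 0.05 in limma, 5034 higher and 4739 lower in mutants, and 10830 passed an unadjusted p of 0.05. Most of these differences were small: the median size was 0.40 on the log2 scale, and 2980 genes were changed at least 1.5-fold (1560 higher, 1420 lower). A change of at least 4-fold was found for 199 higher and 73 lower genes. Higher genes made up 51.5% of the genes called, and 68.2% with median centring in place of loess, where the median of all genes stood at 0.11 on the log2 scale. The number called was 6923 without replicate 2 and 10313 without replicate 1. Of 2507 called genes with 2 or more measured probes, 265 (10.6%) had probes of opposite sign.

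The largest increases were those of Kap3, mthl8 and CG13277. Kap3, which encodes a subunit of the kinesin-II motor, rose by 4.86 on the log2 scale (SD 0.14, 29.0-fold), from 1 probe on the X chromosome at 11228230 to 11228289, and a second Kap3 probe was not well above background in either channel. With no filter on dim probes, which averages both probes, the Kap3 log2 ratio was 2.41. CG13277, now named LSm7, rose by 4.59 (SD 0.18, 24.1-fold), with probes on chromosome 2L at 4.98 and 4.20, and mthl8, a gene of the Methuselah-like receptor family, by 4.54 (SD 0.23). Cyp6a17, a cytochrome P450 gene (4.22), Eip63E, a cyclin-dependent kinase gene (4.13), CG10747 (4.13), the C-type lectin gene lectin-24A (4.12), cn, which encodes the kynurenine hydroxylase of eye pigment synthesis (4.10), CG4998 (4.03) and CG15065, now named BomS5 (4.03), completed the 10 largest increases. The size of the Eip63E increase, and so its place among these, is not settled: its 2 probes lie at the same bases, at 4.90 and 3.37, and the control signal of the latter was not well above background on any array. The control signal of cn was well above background on 3 of 4 arrays, and with Agilent's processed values the ratios of Eip63E and cn were 7.04 and 6.29. With those values lectin-24A stood at 5.55, Kap3 at 5.46 and mthl8 at 5.27, so the first place of Kap3 depends on the processing, and with median centring CG4998 stood at 4.74. The largest decrease was that of CG13813, at -3.44 (SD 0.48, 10.8-fold lower), with probes on chromosome 3L at -3.34 and -3.54. It was followed by CG12256 (-3.06), MED16, which encodes a subunit of the Mediator complex (-3.05), CG14454 (-3.05), the chitinase-like growth factor gene Idgf5 (-3.01), CG2196, now named salt (-3.01), CG13032 (-2.76), CG13694 (-2.75), the odorant receptor gene Or19a (-2.69) and CG33306 (-2.66), and with Agilent's processed values CG13813 stood at -4.37, CG13032 at -3.59 and CG33306 at -3.37. Adjusted p-values of these 20 genes in limma lay between 5.11e-07 and 1.73e-05, with the same sign on all 4 arrays.

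Genes of the cuticle, the chitin-based layer that the late embryo secretes, included lists that were higher in mutants and lists that split in both directions. Osiris genes, which encode transmembrane proteins of cuticle-forming epithelia, were higher in mutants: of 21 measured, 14 rose, 1 fell and 6 did not pass, and 15 were higher and 2 lower adjusted over the list alone. Osi18 rose by 3.70 (SD 0.51), Osi19 by 2.54 (SD 0.64) and Osi2 by 2.16 (SD 0.14), and Osi16 fell (-0.57). The Tweedle cuticle proteins also rose, 15 of 25 with 0 lower and 10 not past the threshold, and 16 and 0 adjusted over the list alone; examples were CG14639, now named TwdlF (1.29, SD 0.44), and CG6447, now named TwdlL (0.90, SD 0.11). Both lists passed in camera with an adjusted p of 0.00141, and with an estimated correlation the adjusted p was 0.771 for the Osiris genes and 0.608 for the Tweedle genes. The mean of the Tweedle list was 0.47, and 0.98 with median centring, where Osi2 stood at 2.90 and CG6447 at 2.00. The mean of the Osiris list was 0.65 on replicate 1 and 1.07, 1.29 and 1.15 on replicates 2 to 4, and that of the Tweedle list was 0.20 on replicate 1 and 0.58, 0.59 and 0.50 on the others.

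The RR-type cuticle proteins, which carry a chitin-binding consensus, split in both directions. Of 94 measured, 40 rose, 32 fell and 22 did not pass, with 40 and 32 adjusted over the list alone (camera adjusted p = 0.844). The neighbouring genes Cpr47Ea (3.21), Cpr47Eb (3.14), Cpr47Ec (2.71) and Cpr47Ed (2.03) rose together, as did Lcp3 (3.35) and Ccp84Aa (2.92), and Lcp1 (-2.07), Cpr49Ad (-1.62) and Acp65Aa (-1.48) fell. The 2 probes of Cpr47Ea were at 1.68 and 4.74, and the latter is the brightest. With no filter on dim probes Cpr47Ed stood at 1.02 and Lcp1 at -1.04, and with Agilent's processed values Cpr47Ed stood at 2.79. Some of these genes have near-identical copies, such as Lcp1 and Lcp2, and whether their probes separate the copies was not tested. Of 27 peritrophin-like chitin-binding proteins, 11 rose, 11 fell and 5 did not pass, with 12 higher and 11 lower adjusted over the list alone, among them Peritrophin-15a (-2.28, SD 0.049), CG7874, now named Mur18B (-1.87; -1.26 with median centring), and obst-J (-1.30). Enzymes of chitin synthesis and modification included kkv, the chitin synthase gene (1.23, SD 0.070), knk, needed for chitin organisation (1.01), and the deacetylase gene ChLD3 (1.30), all higher, and the chitinase gene CG9307, now named Cht5 (-1.02), which was lower. Of 27 measured in that list, 13 rose, 8 fell and 6 did not pass, and 13 and 9 were higher and lower adjusted over the list alone. Catecholamine, melanin and sclerotization genes, a list that also holds yellow-family and prophenoloxidase genes, were mostly higher. In it 13 of 24 were higher, 6 lower and 5 not past the threshold, and 14 and 6 adjusted over the list alone. The tyrosine hydroxylase gene ple (0.79, SD 0.28), the dopa decarboxylase gene Ddc (0.77, SD 0.19), b (0.82, SD 0.17) and the prophenoloxidase gene Bc, now named PPO1 (2.35, SD 0.35), rose, and yellow-f2 fell (-1.04). As a list they did not pass (camera adjusted p = 0.203).

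Of 12 tracheal development genes, 2 were higher, 3 lower and 7 not past the threshold, with 2 and 3 adjusted over the list alone; pri, which encodes small peptides that act in tracheal and epidermal development, fell (-0.94), and SP1070, now named uif, rose (0.74). The pickpocket genes, which encode epithelial sodium channel subunits, had 3 higher, 9 lower and 10 not past the threshold of 22, and 3 and 11 adjusted over the list alone. Among them ppk6 rose (0.96) and ppk7 (-0.37) and ppk23 (-0.32) fell. Of 16 septate junction genes, 4 were higher, 2 lower and 10 not past the threshold, with 4 and 2 adjusted over the list alone, among them Gli (0.61), while nrv2 stood at -0.45 and at 0.12 with median centring. Of 28 muscle genes, 5 were higher, 8 lower and 15 not past the threshold, with 5 and 8 adjusted over the list alone. The actin gene Act79B rose (0.92), and Mlc1, a myosin light chain gene, stood at -0.44 and at 0.61 with median centring. The mean of the muscle list was 0.14, -0.019, -0.057 and -0.13 on replicates 1 to 4.

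Among 26 neuronal and synaptic genes, 3 were higher, 6 lower and 17 not past the threshold, with 3 and 5 adjusted over the list alone. The synaptic glutamate receptor subunit gene GluRIIC rose (0.62) while GluRIIE fell (-0.41). The mean of this list differed between arrays, at 0.21, 0.070, -0.013 and -0.081 on replicates 1 to 4. Of 12 glial markers, 6 were higher, 5 lower and 1 not past the threshold, with 6 and 5 adjusted over the list alone; the glutamate transporter gene Eaat1 fell (-0.84) and moody, a receptor gene of the blood-brain barrier, rose (0.76). Among 32 neuropeptides and peptide hormones, 17 rose, 7 fell and 8 did not pass, with 17 and 7 adjusted over the list alone. The insulin-like peptide genes Ilp3 (0.99) and Ilp2 (0.46) and CG14358, now named CCHa1 (0.68), rose, and Pdf fell (-0.66), with probes at -1.42 and 0.092.

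Digestive enzymes of the midgut were higher in mutants: of 45 measured, 27 rose, 10 fell and 8 did not pass, with 27 and 10 adjusted over the list alone. The trypsin genes lambdaTry (3.36), epsilonTry (2.98) and betaTry (2.12) and the lysozyme gene LysS (2.55) rose, and etaTry fell (-1.33). The list passed in camera with an adjusted p of 0.00208, and its adjusted p was 0.771 with an estimated correlation. Fat body genes had 10 of 17 higher, 3 lower and 4 not past the threshold, with 10 and 3 adjusted over the list alone (camera adjusted p = 0.0841). The larval serum protein gene Lsp1gamma rose by 3.63 (SD 0.19) and RfaBp, now named apolpp, a lipoprotein gene, by 1.52 (SD 0.071; 2.27 with median centring). Fbp1 was 1.52-fold higher in mutants, a size that is not settled, since its control signal was not well above background. Of 13 salivary gland markers, 7 were higher, 2 lower and 4 not past the threshold, with 7 and 2 adjusted over the list alone. Among these PH4alphaSG1 (2.17) and the secretory regulator CrebA (1.05) rose. The glue protein genes Sgs5 and Sgs4 were 2.22-fold and 1.57-fold higher, with no control signal well above background. The folds of Fbp1, Sgs5 and Sgs4 compare channel means after loess and Aquantile normalization and are open to dye bias. They are not strict lower limits, since a dim probe's own control signal can set them. With Agilent's processed values the log2 ratios were 2.46 for Fbp1, 3.93 for Sgs5 and 2.96 for Sgs4.

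Markers of blood cells moved in both directions. Of 12 hemocyte markers, 7 fell, 4 rose and 1 did not pass, with 7 and 4 adjusted over the list alone. The phagocytosis receptor gene CG6124, now named eater (-2.25), the hemolectin gene Hml (-2.01) and the collagen IV genes vkg (-1.28) and Cg25C (-0.88) fell, and the scavenger receptor gene Sr-CI (1.57), lz, the regulator of crystal cells (1.35), and Pxn (0.64) rose. With median centring vkg stood at -0.31 and Cg25C at -0.21. With the brightest probe Sr-CI stood at 0.93, lz at 2.26 and Pxn at 1.25, and with Agilent's processed values eater stood at -3.62, Hml at -3.16, lz at 2.32 and Pxn at 1.54. Antimicrobial and peptidoglycan-recognition proteins were higher, with 14 of 27 higher, 3 lower and 10 not past the threshold, and 14 and 3 adjusted over the list alone. The peptide genes dro2, now named Drsl2 (2.67), Mtk (2.10) and Drs (1.98) rose and CecC fell (-0.86), and with Agilent's processed values dro2 stood at 3.44 and CecC at -2.10, and dro2 at 1.38 with no filter on dim probes. This list passed in camera with an adjusted p of 0.00518, which was 0.608 with an estimated correlation and 0.154 with median centring. Of 11 germ cell and yolk markers, 2 were higher, 3 lower and 6 not past the threshold, with 2 and 3 adjusted over the list alone, and osk fell (-1.32, SD 0.42).

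Cytoplasmic ribosomal protein genes were higher in mutants, by a size that depended on the normalization, with a mean of 0.24 on the log2 scale after loess and 1.04 with median centring. Of 91 measured, 59 rose, 8 fell and 24 did not pass, with 63 and 9 adjusted over the list alone and a median of 0.22 on the log2 scale. RpL8 (0.86), RpLP1 (0.85) and RpS3 (0.72) rose, and RpL22-like fell (-0.62), and with median centring RpL8 stood at 1.95, RpLP1 at 1.89 and RpS3 at 1.66. The log2 control signal was 17.1 for RpL8, 16.6 for RpS3 and 10.6 for RpL22-like, and RpL39, at 17.1, fell (-0.27). Whether these ratios follow signal intensity was not tested, and without swapped dyes a dye effect stays open. The list passed in camera with an adjusted p of 2.73e-06, and its adjusted p was 0.401 with an estimated correlation. Of 13 glycolytic genes, 1 was higher, 3 lower and 9 not past the threshold, with 1 and 2 adjusted over the list alone, and Gpdh stood at -0.38 and, no longer past the threshold, at -0.096 with median centring. Of 24 heat shock protein genes, 5 were higher, 9 lower and 10 not past the threshold, with 7 and 9 adjusted over the list alone; Hsp67Ba rose (1.37) and Hsc70-1 fell (-1.28). The mean of the heat shock list differed between arrays, at 0.055, 0.40, -0.33 and 0.26 on replicates 1 to 4. Of 21 genes of DNA replication and the cell cycle, 4 were higher, 7 lower and 10 not past the threshold, with 4 and 7 adjusted over the list alone. The cyclin gene CycE fell (-0.94) and Orc1, a subunit of the origin recognition complex, rose (2.23, SD 0.71), and the mean of the list was 0.26 on replicate 4 and -0.29, -0.12 and -0.10 on replicates 1 to 3. Of 11 cell death regulators, 3 were higher, 3 lower and 5 not past the threshold, with 3 and 3 adjusted over the list alone, and debcl rose (0.54).

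Of 82 cytochrome P450 genes, 32 rose, 38 fell and 12 did not pass, with 33 and 39 adjusted over the list alone; Cyp4d8 (2.68) and Cyp310a1 (2.47) rose and Cyp4d14 fell (-2.45), and Cyp4d8 stood at 3.81 with Agilent's processed values. Of 35 glutathione S-transferase genes, 8 rose, 16 fell and 11 did not pass, with 9 and 16 adjusted over the list alone; GstE6 (-1.54), GstE7 (-1.48) and GstD8 (-1.12) fell and GstD3 rose (1.62). Of 29 lists tested with camera, 5 passed, all of them higher in mutants, and 0 passed with an estimated correlation. With median centring the pickpocket list also passed, as lower (mean -0.073, camera adjusted p = 0.0153), and the muscle (mean 0.53, adjusted p = 0.00482) and glycolysis lists (mean 0.49, adjusted p = 0.0163) passed as higher. The fat body list passed with the deposited series table (adjusted p = 0.0496) and with no filter on dim probes (adjusted p = 0.0452). With loess, the filter and the preset correlation, the other 24 lists had adjusted p-values between 0.0841 and 0.964. The lists of peritrophin-like, tracheal, heat shock and cytochrome P450 genes had a median, mean and camera direction that were not all of 1 sign. With median centring the means of 8 of the 28 lists turned from below 0 to above 0. These were the peritrophin-like, tracheal, muscle, germ cell, glycolysis, replication, cell death and glutathione S-transferase lists. In that setting the median of all genes was 0.11, and 27 of the 28 list means were higher than with loess. The peritrophin-like (0.096), germ cell (0.050) and glutathione S-transferase (0.067) means stayed below that median, so their change of sign is not a reversal against other genes. By fry, all 29 lists held genes that changed in either direction (p under 0.05 for each, not adjusted over lists). That test does not compare a list with other genes, and 54.6% of all genes passed the threshold, so it sets no list apart.

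The genes next to DHR3 were examined because the mutants carried a deficiency of unstated extent. Of the 15 genes on each side in Release 6 plus ISO1 MT, 22 were measured, of which 9 were lower, 4 higher and 9 not past the threshold, with 9 and 5 adjusted over the list alone. The median was -0.088 (camera adjusted p = 0.179), and 1465 of 10000 random lists matched on intensity had a median as low. The lower genes were CG12909 (-1.19), CG12912 (-0.95), CG12911 (-0.80), JhI-1 (-0.70), the synaptobrevin gene Syb (-0.65), CG12913 (-0.60), the potassium channel gene KCNQ (-0.54), the basement membrane gene Ndg (-0.52) and CG1381 (-0.30); with median centring Ndg stood at -0.070 and CG1381 at 0.065. The higher genes were Obp46a (0.22), Jra (0.21), CG12910 (0.20) and CCS (0.19). The call of Jra was lost without replicate 3 (0.19), and those of Obp46a and CCS were lost without replicate 2 (0.21 and 0.18), 3 (0.19 and 0.17) or 4 (0.19 and 0.17) and with Agilent's processed values (0.19 and 0.17). With no replicate block the calls of Obp46a, CCS and CG12910 were lost. The nearest gene on the left, CG34221, did not pass (0.11, limma adjusted p = 0.0825) except with array quality weights (0.13, limma adjusted p = 0.0221), and the nearest gene on the right had no probe under its name. The median of the list was 0.085 with median centring, where that of all genes was 0.11.

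**Figure D2:**
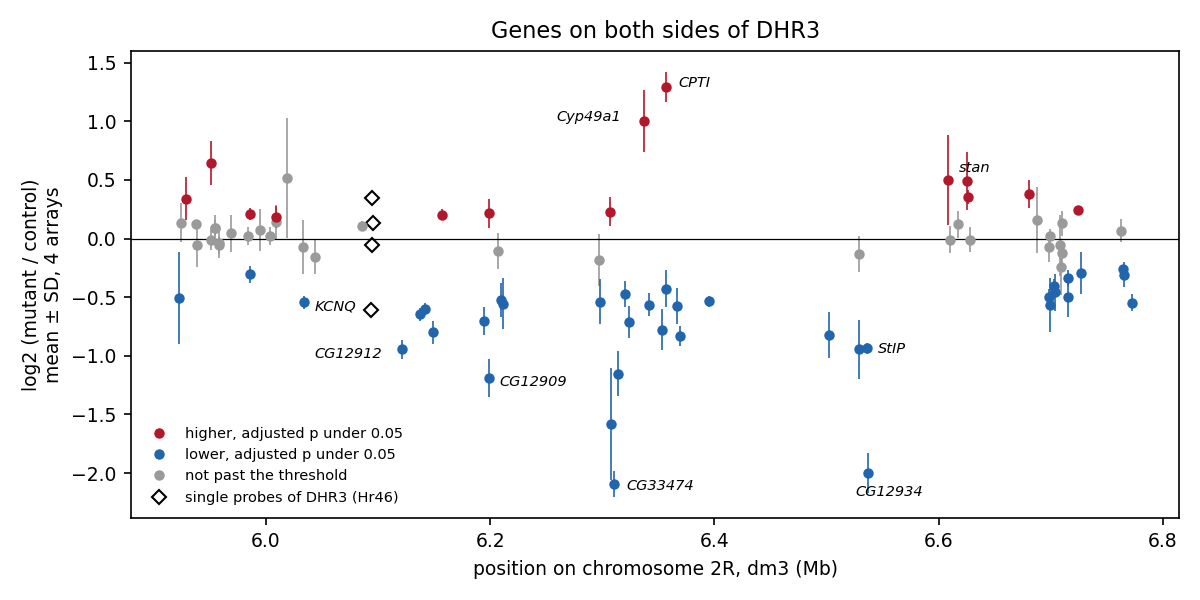
The mean log2 ratio of mutant over control (vertical axis, bars show SD over 4 arrays) against the position of each gene's probes on chromosome 2R in dm3 (horizontal axis, Mb), for genes on both sides of DHR3, whose single probes are drawn as diamonds. Genes up to 53 places to the right of DHR3 have a median of -0.58 and the 30 on the left a median of 0.058. CAP, whose name pools probes on different chromosomes, is left out of the drawing but not of the median.

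Ratios of the 4 arrays were correlated over genes, which are not independent replicates. Pearson's r lay between 0.830, for replicates 1 and 4, and 0.952, for replicates 3 and 4. The lowest r was 0.936 without replicate 1. The 4 arrays lay on 1 slide, so slide could not be tested as a batch.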

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

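The tests in this part were set before the data were examined. In 231 groups of 4 arrays, 12 held an array whose distance from its nearest neighbour took up nearly the whole range of the group, and chance gives about 1 in 20 such groups.

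Among genes, amd, which encodes a protein related to dopa decarboxylase, stood at -0.041 on replicate 1, and the next lowest value was 1.03; its call was lost without replicate 2 (0.71), 3 (0.70) or 4 (0.68). CycB, a mitotic cyclin gene, was at -0.59 on replicate 4 against -1.19 to -1.13. Lcp3 was at 3.69 on replicate 4 against 3.18 to 3.26, and Kap3 at 4.65 on replicate 3 against 4.91 to 4.96. On replicate 1, Ilp3 was at 1.25 against 0.89 to 0.92, CG14240, now named TwdlP, at 0.78 against 0.48 to 0.49, and CCS at 0.046 against 0.22 to 0.25. On replicate 4, GluRIIE was at -0.55 against -0.38 to -0.35, and CG1381 at -0.20 against -0.35 to -0.33. Of the list means, that of the septate junction genes was -0.014 on replicate 4 against 0.064 to 0.075, and that of the salivary gland markers 0.55 on replicate 3 against 0.50 to 0.51. Replicate 3 had 249 outlier spots and the others 66 to 80. No explanation was tested for these values.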

How the results depend on the processing

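The alternatives were set before the data were examined, except the genes on 1 side of DHR3 and the run, which were chosen after seeing the data; where no reason is given, the cause was not tested. Of 3094 values of 194 single genes under 16 alternatives, 3029 kept their direction and side of the threshold, 58 kept their direction and lost the threshold, 1 passed it and 6 changed sign. With median centring nrv2 stood at 0.12, Mlc1 at 0.61, Zeelin1 at 0.25, Pglym78 at 0.26, Eno at 0.69 and CG1381 at 0.065. In that setting the list means were 0.53 for muscle and 0.49 for glycolysis, and the genes next to DHR3 had a median of 0.085. The median of all genes was then 0.11. With the brightest probe DHR3 stood at -0.61 (limma adjusted p = 0.000257), because that probe alone was then used. Without the replicate block, 6738 genes passed, of which 3093 were lower. A change of at least 1.5-fold left 2980 genes, by construction. With an estimated correlation 0 lists passed. The genes next to DHR3 had a median of 0.072 on the left only and -0.60 on the right only (camera adjusted p = 0.964 and 0.0136), and the run on the right -0.58. Leaving out 1 replicate gave 6923 to 10313 genes (3561 to 5305 higher, 3362 to 5008 lower), 5 lists each time, DHR3 at -0.074 to -0.027, ftz-f1 at -0.87 to -0.70, the genes next to DHR3 at -0.16 to -0.078 and a lowest r between arrays of 0.830 to 0.936. Signal over background limits dim genes: 431 genes were detected in 1 channel only.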

Other observations

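Apart from the sign flips of arrays and the run's median under other normalizations, the tests in this part were chosen after the result was seen, as were the gene families, stretches of genes and genes named here outside the rule. Among 144 families of at least 6 genes that share a name stem, 8 passed in camera, of which RpL, RpS and Osi belong to lists already described. With an estimated correlation 0 of the 144 passed (lowest adjusted p 0.974), so each of these calls was lost. All 6 measured Bomanin genes of the BomS group, which encode immune-induced peptides, rose, with a median of 2.69, among them CG15065 (BomS5, 4.03), IM2 (BomS2, 3.85) and CG18107 (BomS4, 2.81) (camera adjusted p = 0.000536). Of 11 Methuselah-like genes, 8 rose, among them mthl3 (3.11, and 4.23 with Agilent's processed values; camera adjusted p = 0.00101). Of 6 genes of the arylalkylamine N-acetyltransferase-like family, 5 fell, with a median of -1.29, among them CG18607 (AANATL4, -2.44) and CG9486 (AANATL2, -2.32; camera adjusted p = 0.00101). Of 10 maltase genes, which the midgut list also holds, 8 rose and 1 fell, among them CG8690 (Mal-A8, 1.80; camera adjusted p = 0.0167), and with median centring the adjusted p was 0.0522. All 6 acyl-CoA-binding protein genes fell, among them CG8628 (Acbp3, -1.04) and CG5804 (-0.72; camera adjusted p = 0.0460), a call that was also lost in 8 of the other settings, among them without replicate 4 (median -0.32).

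In windows of 11 neighbouring genes, the lowest median was -1.13, between CG13656 and CG31098 on chromosome 3R, with 9 genes lower, and the highest was 1.89, between CG18536 and CG15065 on chromosome 2R. A window on chromosome 3L between the cuticle genes Cpr65Av and Cpr65Ay had a median of -0.91, with 8 genes lower.

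On the right of DHR3, 24 of the 33 measured genes up to 53 places away fell, 5 rose and 4 did not pass. The run lay between 6120965 and 6537245 on chromosome 2R of dm3. Its median was -0.58 (interquartile range -0.83 to -0.18, 1.49-fold lower), against 0.058 for 24 measured genes on the left. Members outside the rule included CG33474 (-2.09), StIP (-0.94) and lola (-0.53), and CPTI (1.29) and Cyp49a1 (1.00), which were higher. Of the 5 that rose, Prx2540-2 (0.23) averaged probes at -1.16 and 1.62. CAP, which did not pass, pooled a probe on 2R (-0.23) with a probe on the X chromosome (0.097). Beyond 53 places genes moved in both directions. CG12936 (-0.57), CG11919 (-0.55) and cag (-0.54) were lower, and CG7220 (0.49), Mat1 (0.35) and Cyp12d1-d (2.43) were higher. The end of the run is thus not a boundary past which no gene was lower. A chance run stays open. Each run of 11 to 60 genes was scored by its median times the square root of its number of genes. The length was free, so the score from DHR3 need not be that of the 33 genes above. Of 11336 genes elsewhere, 4 (0.0353%) had beside them a run as low as that from DHR3 (-3.51). All 4 lay at 1 place on chromosome 3R with the same score (-3.75), so they are not separate runs. The criterion set before this count was 0, and a share under 0.05, considered only after it, would have argued against chance. At the run's own length, 0 of 11232 windows elsewhere had a median as low, the lowest being -0.29, but that length was chosen from the values. Normalization or background correction was argued against by a median that came no closer to 0 than -0.40, with median centring. The difference of -0.63 between the run and the left side goes with 1 gene copy in mutants to the right of DHR3. The deficiency may extend there, although the end of the run was chosen from the values. DHR3 itself, whose mutant allele lay over the deficiency by the series title, had a mean of only -0.046, over probes that went both ways. The lesion of that allele is not given, so DHR3 does not settle the copy number. An effect of DHR3 itself on these genes, or of the mutant strain's own alleles, was not tested and stays open.

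Changes of 4-fold or more at single genes, 272 in all, were set against technical explanations. A sequence variant under a probe was argued against as the main source only where a gene had measured probes at other bases. Of all 108 probes changed 4-fold or more in such genes, 28 (25.9%) had a gene whose probes at other bases averaged within 0.5 of 0. These were 3 of 57 in 35 of the 272 genes and 25 of 51 in genes outside the 272. The 272 were picked by the mean over these same probes, so that split was largely fixed by the choice, and only the pooled share weighs here. The pooled share counts a gene once for each such probe. A variant cannot be told apart for the other 237 of the 272, which had no measured probe at other bases. Probes that failed the filter on dim probes were not counted, such as the second Kap3 probe at -0.030, so the pooled share may be too low. Dim signal was argued against by 93.8% of the genes being well above background in both channels on all arrays. Such genes made up 2.26% of chromosome 2 genes and 1.24% of those on chromosomes 3 and X, an odds ratio of 1.85 (95% interval 1.37 to 2.49, Fisher's exact p = 3.99e-05), although neighbouring genes are not independent. This excess may reflect the strain background of the mutant chromosome 2, which the comparison with w1118 does not separate from the loss of DHR3, an effect that was not tested.

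That 9773 genes passed the threshold was tested as a bias of single probes. Over 9165 probes of genes with a probe at other bases, a probe's ratio and the mean of those probes had r = 0.626 (across genes, which are not independent replicates). This argued against such a bias for the larger ratios, which weigh most in r. The bias stays open for small changes and for genes with probes at 1 place, and only 2980 of the called genes were changed at least 1.5-fold. A dye bias of whole transcripts cannot be told apart from the genotype, because 0 arrays had swapped dyes. Turning the sign of whole arrays gives 8 orientations, too few for a share under 0.05: 1 of 8, the real one, gave 9773 genes and the highest other gave 0. For the lists, 3 of 8 gave at least as many as the real 5, and the highest other gave 6. Strain and developmental age, which can differ between these embryos within the 4 h of egg laying, were not tested and stay open beside the genotype.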
